A study of Solanum lycopersicum with 8 samples.

How the data were processed

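RNA was sequenced from tomato (Solanum lycopersicum) leaves treated with tunicamycin, an antibiotic that blocks N-linked protein glycosylation in the endoplasmic reticulum (ER), or from control leaves, at 2 h and at 6 h. There were 4 groups of 2 biological replicates each, 8 libraries in all. The labels name a directional library kit and total RNA. Whether the counts are strand-specific, and which aligner, counting program, genome build and annotation were used, are not given in the sources used here. Trimmomatic 0.40 is named in the submitters' processing notes.

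The deposited count table holds raw counts of reads, as whole numbers, for 45845 RefSeq transcripts of 29081 genes, one column for each library. The authors also deposited 3 comparison tables, in which the fold changes are on the log2 scale and the average abundance is in log2 CPM (counts scaled to a common library total), per the file headers. In the same deposited tables the F column is a score, the F statistic of the authors' test, and the remaining columns are its p-value and false discovery rate. The test that made these tables is not named. In the authors' table for 2 h, 1 fold-change cell could not be read as a number and was left out. Reads appear to have been counted for every variant that they could belong to, although the counting program is not known: for genes with at least 2 transcripts, the median ratio of the lower to the higher count of the 2 largest variants was 0.961. Counts of called transcripts hold some genes more than once, and counts of genes are given beside them. Gene symbols and descriptions came from the deposited tables. Of the deposited transcripts, 92.6% had a symbol found in a RefSeq gene table, from which no coordinates were taken, since the build of the counts is not given.

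Totals per library ran from 4689769 to 122784850 counts. Each group held 1 deeper and 1 shallower library, and the deeper held between 5.49 and 9.98 times the counts of the shallower. The deeper library was replicate 2 in both control groups and replicate 1 in both tunicamycin groups. Within-depth values, from the 2 deeper or the 2 shallower libraries of a comparison, are therefore given beside pooled ones for the main genes and lists.

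Counts were analysed with edgeR 4.0.16 in R 4.3.3. Transcripts were kept by filterByExpr with the 4 groups (minimum count 10, minimum total count 15), which left 34483 transcripts of 20280 genes. Libraries were scaled by TMM. A model with 1 mean per group was fitted to all 8 libraries by robust quasi-likelihood, with 4 residual degrees of freedom, and each comparison was a contrast in it, two-sided. Transcripts with a Benjamini-Hochberg adjusted p under 0.05 were called. The common biological coefficient of variation was 0.353, and the prior degrees of freedom came to 10.6. Abundance is given as TMM-scaled CPM, as mean ± SD of the 2 libraries. The error of a log2 fold change is a standard error, its absolute value divided by the square root of the F statistic. Plotted log2 CPM values carry a prior count of 2.

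Before the data were examined, 5 comparisons were fixed: tunicamycin against control at 2 h and at 6 h, 6 h against 2 h in each arm, and the difference of the tunicamycin effect between the times. Also fixed then were 27 gene lists, matched on the descriptions, and the rule for named genes. The lists cover ER folding and quality control, secretion, stress, hormones, transcription factor families, the clock, photosynthesis and markers of vascular, dividing and epidermal cells. The rule took, at each time, the 10 described genes with the largest called change in each direction, with a mean log2 CPM of at least 1 and both treated libraries beyond both control libraries. It added the 3 members of each list with the smallest adjusted p, passing or not. For the other comparisons it took 5 genes in each direction, and where none passed, those with the smallest p. Some patterns take in genes of another function, such as F-box proteins with PP2 in their names among the vascular markers.

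Lists were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01, over 135 tests together. The tests were repeated with an estimated correlation, with fry, and with 1 transcript for each gene. Counts "adjusted over the list alone" apply the Benjamini-Hochberg adjustment to a list's transcripts only. Overlaps of called transcripts were tested with Fisher's exact test across transcripts, which are not independent replicates.

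The procedure was tested on simulated data made from the same libraries, with 2-fold, 4-fold and 8-fold changes put into 200 transcripts. These were drawn from transcripts with a mean log2 CPM of at least 1, so recovery at lower counts was not measured. Counts of each transcript were drawn separately, without reads shared between variants of a gene. At 2 h it recovered 2.99% of the 2-fold, 61.2% of the 4-fold and 90.9% of the 8-fold changes, with 103 true and 13 false calls. At 6 h it recovered 1.49%, 55.2% and 92.4%, with 99 true and 11 false calls. At both times the false calls were a larger share of all calls than the adjusted p threshold aims at. Within a group, replicates differed far beyond counting error: the chi-square per degree of freedom ran from 17 to 231.

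Alternatives covered RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (1 CPM and 10 reads in 2 libraries), only the libraries compared, transcripts summed to genes, an absolute log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were a depth term, 1 transcript for each gene, removal of ribosomal RNA, and the libraries compared without a low-count filter. With 2 libraries in each group, other splits of the samples could not be tested, and no group was large enough for a test of outlying samples.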

Results

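Tomato leaves were sampled after 2 h and 6 h of ER stress and compared with control leaves of the same time, as the series design states. Each of the 4 groups had 2 libraries, so n = 2 for every mean ± SD below. Totals, replicate 1 then replicate 2, were 4689769 and 46824604 counts for control 2 h and 44584773 and 6399672 for tunicamycin 2 h. They were 21030108 and 122784850 for control 6 h and 91835307 and 16729450 for tunicamycin 6 h. Across transcripts, Pearson's r of log2 CPM lay between 0.92 and 0.935 within groups and between 0.881 and 0.959 between groups, so libraries of a group were not closer to each other than to all other libraries. Ribosomal RNA took 2.56% of the counts of tunicamycin 6 h replicate 2, against 0.115% to 0.677% in the other libraries.

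At 2 h, 3 of 62 genes of jasmonate synthesis and response were called lower in tunicamycin leaves than in control leaves. The transcript of aos (allene oxide synthase, which starts the branch of lipid oxidation that leads to jasmonate) stood at 48.3 ± 14.3 CPM in control leaves and 2.44 ± 1.09 CPM in tunicamycin leaves. Its log2 fold change was -4.44 ± 0.45 (adjusted p = 0.00241), at -5.09 between the deeper and -3.55 between the shallower libraries. Of 21 alternatives it passed in 19, and ended without control 2 h replicate 2 and without tunicamycin 2 h replicate 1 (highest adjusted p = 0.261, log2 from -4.86 to -3.93). AOC (allene oxide cyclase, the next enzyme of that branch) went from 70.5 ± 14.6 to 10.8 ± 0.202 CPM (log2 -2.71 ± 0.44, adjusted p = 0.0423). JAZ2, a repressor of jasmonate signalling, went from 85.7 ± 40.1 to 13.9 ± 0.611 CPM (log2 -2.62 ± 0.37, adjusted p = 0.0307). The other named genes that fell were LOC101261097 (the anion channel SLAH2, log2 -2.92), LOC101246157 (GRAVITROPIC IN THE LIGHT 1, -2.90), LOC101261402 (a UDP-glucose 6-dehydrogenase, which makes a sugar nucleotide for the cell wall, -2.81), LOC101253022 (polyamine oxidase 1, -2.70), LOC101246341 (an esterase, -2.58) and LOC101251665 (4-coumarate--CoA ligase-like 5, -2.36). LOC101245413 (an uncharacterized protein, chosen after its values were seen) gave -2.19 (adjusted p = 0.0332). The gene that rose was LOC101260261 (wound-induced protein 1), from 1.22 ± 0.00319 to 23.4 ± 17.1 CPM (log2 4.28 ± 0.59, adjusted p = 0.0307). Among the 21 alternatives the call of AOC ended in 9, those of LOC101261097 and LOC101245413 in 8, those of LOC101261402 and LOC101246341 in 7, and those of the other 5 genes besides aos in 6.

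In all, 16 transcripts of 11 genes passed in edgeR at 2 h, 1 up and 15 down, and 2501 of 34483 had an unadjusted p under 0.05. The count was 3 with the replicate number as a block and 53 with a depth term, which kept all 16, while it was 308 in DESeq2 and 1 in limma-voom. It fell to 6 without control 2 h replicate 1, to 0 without control 2 h replicate 2 and to 0 without tunicamycin 2 h replicate 1, and rose to 183 and 92 without control 6 h replicates 1 and 2 and to 56 without tunicamycin 6 h replicate 2; without tunicamycin 2 h replicate 2, 13 were called, 12 up and 1 down, of which 2 were among the 16. With no low-count filter 679 were called, 263 up and 416 down.

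The jasmonate list held 62 measured genes at 2 h. Of these, 3 fell, none rose and 59 did not pass, with 11 lower when adjusted over the list alone. The list as a whole was lower by camera (median log2 -0.03, adjusted p = 0.0107), a call that ended with an estimated correlation (adjusted p = 0.91) and without tunicamycin 2 h replicate 2 (adjusted p = 0.406). Of the 94 genes matched to the phenylpropanoid and flavonoid list, LOC101251665 fell and 93 did not pass, with 4 lower when adjusted over the list alone. By camera this list was lower (median -0.42, adjusted p = 0.00633, and 0.91 with an estimated correlation). LOC101251665 entered the list by its description alone, so its place in this pathway is not established here.

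ER folding genes did not pass at 2 h. None of the 15 chaperone genes, 16 disulfide isomerase and oxidoreductin genes, 20 ER-associated degradation genes, 19 unfolded protein response regulators or 29 N-glycosylation genes was called, over all genes or adjusted over the list alone. BiP/grp78, the main HSP70-type chaperone of the ER lumen, stood at 58.8 ± 1.15 CPM in control and 35.5 ± 1.65 CPM in tunicamycin leaves (log2 -0.73 ± 0.40, adjusted p = 0.755). LOC101252027, a glucosyltransferase that checks glycoprotein folding, gave -0.56 ± 0.32, and the protein disulfide-isomerase LOC101262222 gave -0.69 ± 0.34. List medians were -0.19 for chaperones, -0.25 for disulfide isomerases, 0.15 for degradation, 0.07 for regulators and 0.00 for N-glycosylation. Of these 5 lists only degradation passed by camera, upward (adjusted p = 0.0349, and 0.91 with an estimated correlation), at -0.17 between the deeper and 0.47 between the shallower libraries. That call ended without control 2 h replicate 1 (adjusted p = 0.519), without tunicamycin 6 h replicate 2 (0.0558) and, with the direction turned, without tunicamycin 2 h replicate 2 (0.96).

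Heat shock proteins and heat stress factors outside the ER were higher as a list at 2 h, with 49 of 73 genes above zero and none called singly. The list median was 0.27 (adjusted p = 1.91e-06, and 0.0499 with an estimated correlation), at 0.39 between the deeper and 0.08 between the shallower libraries. With 1 transcript for each gene and an estimated correlation it no longer passed (adjusted p = 0.668). LOC101255240, of the cytosolic HSP70 family, gave 1.83 ± 0.42 (adjusted p = 0.185), and LOC101248279, a class III small heat shock protein, gave 1.41 ± 0.38 (adjusted p = 0.272). Autophagy genes were also higher as a list, 33 of 37 above zero (median 0.44, adjusted p = 5.36e-06, and 0.91 with an estimated correlation), with LOC101259351 (autophagy-related protein 18f) at 1.49 ± 0.43 (adjusted p = 0.334). Of the calcium and early wound or touch genes none was called, and 1 was higher when adjusted over the list alone. The zinc finger genes LOC101254884 and LOC101256572, both described as ZAT10 or ZAT10-like, stood at 2.31 ± 0.45 (adjusted p = 0.0981) and 2.94 ± 0.67 (adjusted p = 0.239).

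Another 7 lists passed by camera at 2 h. Plant cell death proteases (median -0.70, adjusted p = 0.0157), proteasome subunits (-0.22, 0.00727), cytosolic ribosomal proteins (-0.15, 0.0416), auxin response (-0.07, 0.0285) and the calcium and wound list (-0.16, 0.0096) were lower. Photosystem and Rubisco genes (0.19, 0.0355) and clock genes (0.61, 0.0355) were higher. With an estimated correlation the adjusted p was 0.928 for ribosomal proteins and 0.91 for each of the other 6. Of the lists that passed at 2 h, only the heat shock and autophagy lists did so with each library left out in turn. Without control 2 h replicate 1 the proteasome call ended (0.057) and ribosomal proteins turned higher (0.943). Without control 2 h replicate 2 the calls ended for cell death (0.111), proteasome (0.0503), auxin (0.213), calcium (0.0701) and clock (0.182), and photosystems turned lower (0.971). Without tunicamycin 2 h replicate 1 they ended for cell death (0.563) and proteasome (0.316). Without tunicamycin 2 h replicate 2 they ended for phenylpropanoids (0.176), auxin (0.439), calcium (0.118) and clock (0.356), and photosystems (0.762) and ribosomal proteins (0.727) turned. Smaller losses came without control 6 h replicate 2 (auxin, 0.0508), tunicamycin 6 h replicate 1 (ribosomal, 0.051) and tunicamycin 6 h replicate 2 (ribosomal 0.0612 and clock 0.0688).

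**Figure D1:**
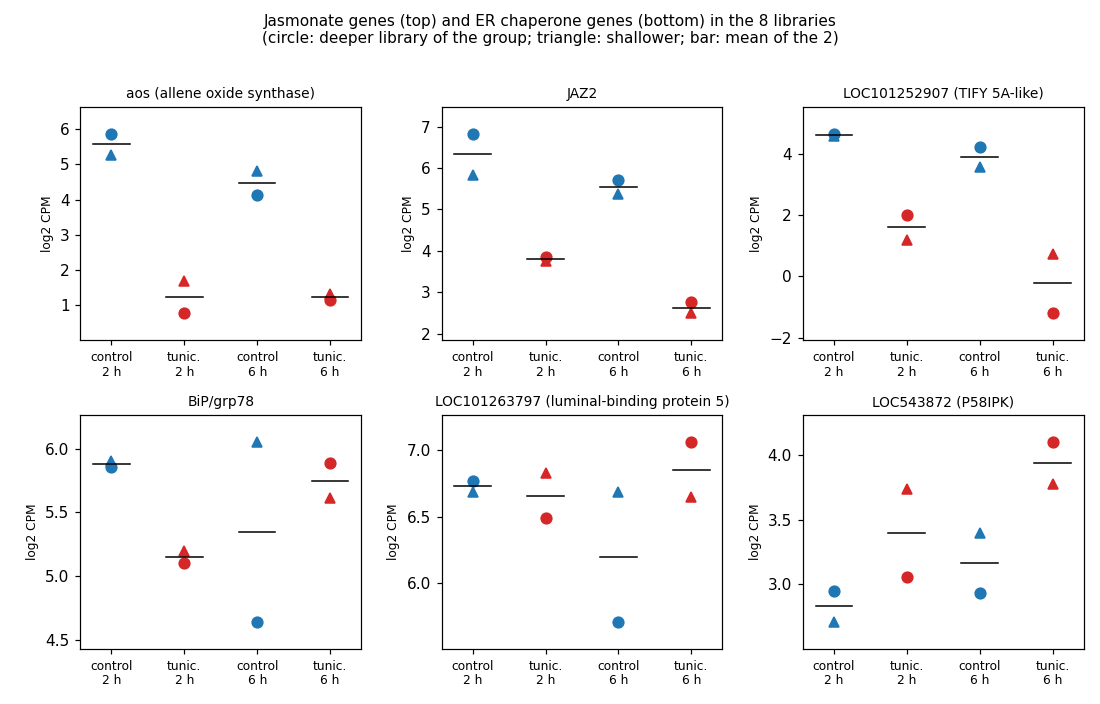
Log2 CPM of 3 jasmonate genes (top) and 3 ER chaperone genes (bottom) in the 8 libraries. The horizontal axis gives the group, circles and triangles are the deeper and the shallower library of each group, and bars are means of 2. For aos the tunicamycin libraries lie between 0.78 and 1.70 and the control libraries between 4.14 and 5.87, while for LOC101263797 the libraries at 6 h overlap (controls 5.71 and 6.69, tunicamycin 6.65 and 7.06).

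At 6 h, 6 of the 62 jasmonate genes were called lower in tunicamycin leaves. LOC101252907 (TIFY 5A-like, of the JAZ repressor family) stood at 15.4 ± 4.91 CPM in control and 1.02 ± 0.882 CPM in tunicamycin leaves (log2 -4.17 ± 0.60, adjusted p = 0.0114). For aos the log2 fold change was -3.30 ± 0.41 (adjusted p = 0.00992), at -2.97 between the deeper and -3.49 between the shallower libraries, and for JAZ2 it was -2.92 ± 0.38 (adjusted p = 0.00992). Chosen after their values were seen, loxD (a chloroplast lipoxygenase that feeds jasmonate synthesis) and SLJAZ3 gave -2.48 and -2.29, both called. Among the 21 alternatives the call ended in 6 for SLJAZ3, in 3 for loxD and in 2 for each of the other 3 genes. Of the list, none rose and 56 did not pass, with 8 lower when adjusted over the list alone. AOC, called lower at 2 h, was among those that did not pass. It stood at 40.9 ± 18.4 CPM in control and 23.7 ± 12.9 CPM in tunicamycin leaves. Its libraries at 6 h overlapped (log2 CPM 5.75 and 4.80 in controls, 3.87 and 5.04 with tunicamycin). The list as a whole did not pass (median 0.06, mean -0.38, camera downward with adjusted p = 0.881).

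Other genes fell at 6 h as well. GA2ox3, which inactivates gibberellins, went from 14.8 ± 5.35 to 1.13 ± 0.245 CPM (log2 -3.67 ± 0.42, adjusted p = 0.00992). ER5, an ethylene-responsive late embryogenesis-like protein, gave -2.91 ± 0.42, and the transcription factor genes LOC101246746 (ERF027-like) and LOC101248897 (DREB1F-like) gave -2.88 ± 0.40 and -3.43 ± 0.66. LOC101264635 (described as an 11-beta-hydroxysteroid dehydrogenase, -3.47), LOC101265598 (ABC transporter F family member 4, -3.08), LOC101253022 (polyamine oxidase 1, -2.95) and LOC101251665 (4-coumarate--CoA ligase-like 5, -2.16) fell too. Of the 133 calcium and wound genes, 3 fell and 130 did not pass, with 7 lower when adjusted over the list alone: LOC101245711 (calcium-binding CML19, -2.58), LOC101255079 (calmodulin-binding protein 60 B-like, -1.98) and LOC101267354 (calmodulin-binding protein 60 C, -2.13). Of 56 WRKY genes, LOC101258576 (WRKY 53, -1.90) and LOC101246812 (WRKY 40, -1.94) fell and 54 did not pass, with 3 lower when adjusted over the list alone. Of 41 NAC genes NACMTF3 fell (-2.08), and of 129 auxin response genes LOC543701 fell (-2.58). Many of these calls depended on the setting: among the 21 alternatives they ended in 15 for LOC101248897 and LOC101246812, 14 for LOC101267354, 13 for LOC101258576, 9 for LOC101255079, 7 for LOC101264635, 6 for NACMTF3 and 2 or 3 for each of the other 8 genes.

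The calcium and wound list (median -0.16) and the WRKY list (median -0.33) were lower by camera, each with adjusted p = 8.6e-05, and 0.91 with an estimated correlation. The WRKY call ended without tunicamycin 6 h replicate 2 (adjusted p = 0.0727). Plant cell death proteases were lower as a list (median -1.02, adjusted p = 6.95e-05, and 0.63 with an estimated correlation), with none of 9 called and 1 lower when adjusted over the list alone. That member was LOC101247995 (metacaspase-1-like), at -1.47 ± 0.35 (adjusted p = 0.128 over all genes). Abscisic acid and dehydration genes were lower as a list (median -0.08, adjusted p = 0.0323, and 0.91 with an estimated correlation), with ER5 the 1 of 116 called. That list's call ended without tunicamycin 2 h replicate 2 (0.0664), control 6 h replicate 2 (0.739) or tunicamycin 6 h replicate 2 (0.417). The cell death and calcium lists passed with each of the 8 libraries left out in turn.

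At 6 h, 7 genes were called higher in tunicamycin leaves than in control leaves. SAUR78 (LOC101268293) stood at 3.44 ± 1.26 CPM in control and 24.1 ± 12 CPM in tunicamycin leaves (log2 2.84 ± 0.49, adjusted p = 0.0295). At 2 h it stood at 25.5 ± 6.78 and 30.7 ± 17.5 CPM, and in control leaves its fall from 2 h to 6 h was itself called in edgeR (log2 -2.91, adjusted p = 0.0219). ARGOS, named for its part in organ size, stood at 2 ± 0.123 CPM in control and 15 ± 7.84 CPM in tunicamycin leaves (2.91 ± 0.53, adjusted p = 0.0343). The transcription factor genes LOC101262125 (bHLH87-like), LOC101253163 (zinc finger protein 8) and LOC101266900 (HBI1) gave 2.91 ± 0.54, 2.50 ± 0.46 and 1.87 ± 0.37. LOC101250521 (cation/calcium exchanger 1-like) gave 2.07 ± 0.34 and LOC101248236 (peroxidase 44-like) 1.75 ± 0.33. Of the auxin list, SAUR78 and ARGOS were the 2 of 129 genes called higher. The calls of the 7 genes ended in 13 of the 21 alternatives for LOC101266900, 12 for LOC101253163, 11 for LOC101248236, 8 for ARGOS and LOC101262125, 6 for SAUR78 and 5 for LOC101250521.

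ER folding genes did not pass at 6 h either. None of the 15 chaperone genes, 16 disulfide isomerase genes, 20 degradation genes, 19 regulators or 29 N-glycosylation genes was called over all genes, and adjusted over the list alone 1 disulfide isomerase was higher and 1 regulator was lower. The isomerase, LOC101244079, went from 0.47 ± 0.0953 to 8.58 ± 10.8 CPM (log2 4.17 ± 1.01, adjusted p = 0.156 over all genes), at 4.81 between the deeper and 1.16 between the shallower libraries. LOC101263797 (luminal-binding protein 5, a BiP) stood at 77.8 ± 36.2 CPM in control and 117 ± 23.5 CPM in tunicamycin leaves (log2 0.59 ± 0.38, adjusted p = 1), at 1.36 between the deeper and -0.04 between the shallower libraries. LOC543872 (P58IPK, a co-chaperone of BiP) gave 0.78 ± 0.37 and LOC101256620 (ERDJ3A, another) gave 1.13 ± 0.47. The regulator was LOC101264896 (BAG family chaperone regulator 1), at -1.44 ± 0.35 (adjusted p = 0.135 over all genes). List medians were 0.15 for chaperones, 0.14 for disulfide isomerases, 0.01 for degradation, -0.14 for regulators and 0.01 for N-glycosylation. The disulfide isomerase list passed by camera (adjusted p = 0.0285, and 0.91 with an estimated correlation), at 0.41 between the deeper and -0.05 between the shallower libraries. Of the 8 settings with 1 library left out it passed only without control 6 h replicate 1 (adjusted p = 0.000113), and its direction turned without control 6 h replicate 2 (0.59).

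In all, 111 transcripts of 80 genes passed in edgeR at 6 h, 7 up and 104 down, and 1403 had an unadjusted p under 0.05. The count was 72 with the replicate number as a block, 161 with a depth term and 38 with transcripts summed to genes, and with only the 4 libraries of 6 h in the fit it was 0, with 1327 at an unadjusted p under 0.05 (DESeq2 396 and limma-voom 104 in the 8 libraries). It was 66, 38, 55 and 70 without control 2 h replicates 1 and 2 and tunicamycin 2 h replicates 1 and 2, 194 without control 6 h replicate 1, 0 without tunicamycin 6 h replicate 1 (1592 at an unadjusted p under 0.05) and 33 without tunicamycin 6 h replicate 2 (17 up and 16 down); 118 were called without control 6 h replicate 2, of which 66 were among the 111.

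Photosystem and Rubisco genes (median 0.28, adjusted p = 0.0115), cytosolic ribosomal proteins (0.14, 0.000338) and dividing cell markers (0.15, 0.0257) were higher as lists at 6 h, none with a called member and each at 0.91 with an estimated correlation. Between the deeper libraries the photosystem median was -0.31 and between the shallower 0.78, and the shallower tunicamycin library was the one with 2.56% ribosomal RNA. Without that library (tunicamycin 6 h replicate 2) the photosystem list was lower (adjusted p = 0.00195), and without control 6 h replicate 1 it did not pass (0.416). Ribosomal proteins turned lower without control 6 h replicate 2 (0.000207) and, without passing, also without tunicamycin 6 h replicate 2 (0.433), and dividing cell markers turned lower without passing when either was left out (0.887 and 0.727).

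The remaining lists did not pass by camera at either time. At 2 h and 6 h the medians were 0.03 and 0.13 for the ER translocon and signal peptide processing, -0.05 and 0.10 for COPI and COPII coats, 0.01 and 0.06 for antioxidant enzymes, -0.17 and -0.06 for pathogenesis-related proteins and 0.08 and -0.03 for ethylene. They were 0.21 and -0.11 for NAC factors, -0.20 and -0.08 for vascular markers and 0.13 and 0.04 for epidermal markers. For ethylene, 5 of 155 genes fell at 6 h, among them ER5 and LOC101246746, and 11 were lower and 2 higher when adjusted over the list alone, while at 2 h none was called and 3 were lower and 4 higher over the list alone. At 2 h, 1 antioxidant gene was lower and 2 vascular markers were higher and 1 lower over the list alone.

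The tunicamycin effects at the 2 times were then compared directly. Of the transcripts called lower, 8 (7 genes) were shared, against 0.0452 if the calls were independent (Fisher's exact test across transcripts, p = 3.29e-17). The shared genes were aos, JAZ2, LOC101261097, LOC101253022, LOC101246341, LOC101251665 and LOC101245413. Across 15435 genes the log2 fold changes of the 2 times gave Pearson's r = 0.403, where genes are not independent replicates. No transcript passed in the test of the difference between the times by edgeR (761 at an unadjusted p under 0.05), DESeq2 or limma-voom, while 93 passed in edgeR with no low-count filter (37 up and 56 down), 38 without control 6 h replicate 1 and 2 without tunicamycin 2 h replicate 2. The smallest p values belonged to LOC101264635 (log2 -3.80 ± 0.81), LOC101257056 (LOB domain-containing protein 40, 2.28 ± 0.51), LOC101267103 (malate synthase, -2.62 ± 0.64), LOC101262125 (bHLH87-like, 3.05 ± 0.76) and LOC101251205 (ATHB-15, 1.94 ± 0.50), each with adjusted p = 1. The count of shared transcripts was 0 without control 2 h replicate 2, tunicamycin 2 h replicate 1 or tunicamycin 6 h replicate 1, 3 without tunicamycin 2 h replicate 2, 54 and 42 without control 6 h replicates 1 and 2, 26 with a depth term and 2 with the replicate number as a block.

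The comparison of 6 h with 2 h within tunicamycin leaves, one of the 3 that the authors tabulated, holds harvest time as well as treatment. Several small heat shock protein genes and several clock-related genes were among those called lower at 6 h. LOC544282 (class II small heat shock protein Le-HSP17.6) went from 670 ± 155 to 8.62 ± 5.15 CPM (log2 -6.26 ± 0.71, adjusted p = 0.000888) and LOC101248279 from 198 ± 52.9 to 4.98 ± 0.193 CPM (-5.31 ± 0.45, adjusted p = 4.67e-05). LOC101255972 (REVEILLE 7, a clock-related MYB factor that peaks in the morning in other plants) went from 53 ± 10.5 to 0.948 ± 0.182 CPM (-5.75 ± 0.43, adjusted p = 4.57e-05). LOC101253545 (REVEILLE 8), LOC101261079 (REVEILLE 1) and LOC101261662 (LHY), chosen after their values were seen, gave -5.96, -4.84 and -3.79, all called. Their calls were not followed through the alternatives. ELIP (early light inducible protein) and the pectinesterase gene LOC101245007 gave -5.14 and -5.25. The largest rises were those of LOC101248557 (the protease AED3, 3.97 ± 0.63), LOC101265401 (POLLENLESS 3-LIKE 2, 3.81 ± 0.74), Cyp-3 (cysteine proteinase 3, from 3.48 ± 2.19 to 30 ± 16.6 CPM), LOC101264700 (elongation factor 1-alpha, 2.83 ± 0.54) and LOC101268000 (bHLH61, 2.71 ± 0.46). Among the 21 alternatives the call ended in 9 for LOC101265401, 4 for Cyp-3 and LOC101264700, 3 for LOC101248557, 2 for LOC101268000 and 1 for ELIP and LOC101245007. Of 73 heat shock genes 18 fell, none rose and 55 did not pass, with 30 lower when adjusted over the list alone (median -0.56, adjusted p = 1.24e-16, 0.0281 with an estimated correlation, and 0.0937 with 1 transcript for each gene as well). Of 29 clock genes 7 fell, 1 rose and 21 did not pass (median -0.51, adjusted p = 1.75e-10, 0.415 with an estimated correlation, and 0.0398 with 1 transcript for each gene).

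In all, 208 transcripts of 161 genes passed in edgeR in that comparison, 28 up and 180 down, and 353 with a depth term, which kept 206. The count was 134 and 109 without control 2 h replicates 1 and 2, 65 without tunicamycin 2 h replicate 1, 613 and 500 without control 6 h replicates 1 and 2 and 121 and 101 without tunicamycin 6 h replicates 1 and 2, while LOC544282, LOC101248279 and LOC101255972 passed under all 21 alternatives.

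Control leaves also differed between 6 h and 2 h, the background for the comparison above. LOC544282 went from 609 ± 112 to 8.85 ± 7.27 CPM (log2 -6.13 ± 0.70, adjusted p = 0.00149), LOC101255972 from 23.9 ± 9.28 to 0.951 ± 0.0635 CPM (-4.62 ± 0.41, adjusted p = 0.000158) and ACO5, an enzyme of ethylene synthesis, from 141 ± 27.5 to 5.73 ± 1.58 CPM (-4.63 ± 0.63, adjusted p = 0.00686). ELIP and the class IV heat shock gene LOC101256272 gave -5.18 and -4.90. GIGANTEA (LOC101255788), a clock gene of the evening, rose from 25.8 ± 15.8 to 134 ± 50 CPM (2.36 ± 0.44, adjusted p = 0.0373), and LOC101247899 (a light-harvesting complex-like protein) by 2.92 ± 0.50. The call ended in 9 of 20 alternatives for GIGANTEA, 6 of 19 for LOC101247899, 3 of 20 for ACO5 and 2 of 20 for ELIP. Of 73 heat shock genes 12 fell, with 21 lower when adjusted over the list alone (median -0.32, adjusted p = 1.7e-08, 0.0499 with an estimated correlation, and 0.0937 with 1 transcript for each gene as well), and of 29 clock genes 5 fell and 1 rose, 14 above and 15 below zero (median -0.24, adjusted p = 1.62e-11, but 0.407 with an estimated correlation and 0.113 with 1 transcript for each gene). Of the transcripts lower at 6 h, 73 (48 genes) were called in both arms, against 0.475 if independent (Fisher's exact test across transcripts, p = 4.49e-156). Across genes, Pearson's r between the arms was 0.545.

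In control leaves 93 transcripts of 64 genes passed in edgeR, 2 up and 91 down, and 125 with a depth term, which kept 91. The count was 23 and 47 without control 2 h replicates 1 and 2 and 252 without control 6 h replicate 1; 65 were called without control 6 h replicate 2, of which 48 were among the 93. By camera, 5 ER lists were lower at 6 h in control leaves: chaperones (median -0.37, adjusted p = 0.0157), disulfide isomerases (-0.26, 0.0415), N-glycosylation (-0.33, 0.00175), the translocon list (median -0.18, mean 0.09, 0.0461) and the regulators (median 0.06, mean -0.23, 0.0176). With an estimated correlation the adjusted p was 0.321 for N-glycosylation and 0.91 for the other 4. For chaperones the median was -0.83 between the deeper and 0.00 between the shallower libraries, and the call ended without control 2 h replicate 2 (0.0951), tunicamycin 2 h replicate 2 (0.0593) or control 6 h replicate 2 (0.515). The regulators' call ended without control 2 h replicate 1 (0.171) or control 6 h replicate 2 (0.0601), and that of N-glycosylation without control 6 h replicate 2 (0.0724). Disulfide isomerases passed only without control 6 h replicate 1 (0.00125) and turned without control 6 h replicate 2 (0.79). The translocon list passed only without tunicamycin 2 h replicate 1 or control 6 h replicate 1, and without control 6 h replicate 2 its adjusted p was 0.929.

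**Figure D2:**
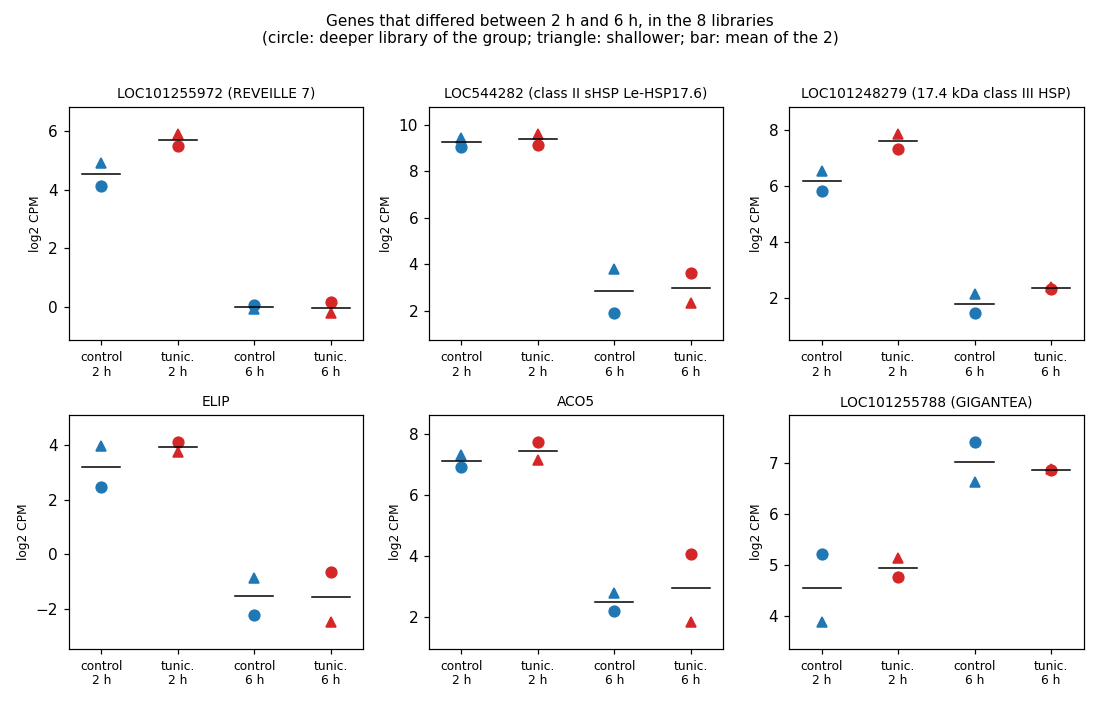
Log2 CPM of 6 genes that differed between 2 h and 6 h, in the 8 libraries. The horizontal axis gives the group, circles and triangles are the deeper and the shallower library of each group, and bars are means of 2. For LOC101255972 (REVEILLE 7) the libraries of 2 h lie between 4.12 and 5.92 and those of 6 h between -0.21 and 0.16, in both arms.

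The authors' tables call 817 transcripts at 2 h (355 up and 462 down), 124 at 6 h (11 up and 113 down) and 1141 between 6 h and 2 h of tunicamycin (399 up and 742 down), at a false discovery rate under 0.05. Of the 16, 111 and 208 transcripts called here, the authors' tables call 16, 99 and 207, and all have the same sign there. An edgeR fit of only the libraries compared, with no low-count filter, called 871, 132 and 1220 transcripts, among them all 817, 124 and 1141 of the authors' tables, and Pearson's r of the log2 fold changes across transcripts was 1 in each.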

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

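The 7 tests of explanations given below were all chosen after the results they measure had been seen, as were leaving out single libraries for the lists and the fit with 1 transcript for each gene, while the tests of the difference between the times were fixed before the data were examined. Of the 7, the 2 tests of depth as the cause of a difference and the test of a fading handling response took the place of earlier ones, the first 2 because the design or the choice of genes had decided the outcome and the last because it had left the matter undecided. By camera with the preset correlation, the tunicamycin effect differed between 2 h and 6 h for 10 of the 27 lists, although no single transcript passed that test in edgeR (761 at an unadjusted p under 0.05, 0 adjusted calls in DESeq2 and limma-voom, and 93 in edgeR with no low-count filter). The list of heat shock proteins and heat stress factors outside the ER was higher with tunicamycin at 2 h (median log2 0.27) and not at 6 h (-0.03), with 53 of 73 genes lower in the difference (adjusted p = 3.1e-07, and 0.0499 with an estimated correlation). Autophagy genes went from 0.44 to 0.03, with 31 of 37 lower in the difference (adjusted p = 0.0107). ER chaperones went from -0.19 to 0.15, with 14 of 15 higher (0.0313). Disulfide isomerases went from -0.25 to 0.14, with 13 of 16 higher (0.0257). Proteasome subunits went from -0.22 to -0.02, with 42 of 51 higher (0.0157). Cytosolic ribosomal proteins went from -0.15 to 0.14, with 189 of 228 higher (4.94e-06). Phenylpropanoid genes went from -0.42 to -0.04, with 56 of 94 higher (0.0251), and auxin response genes from -0.07 to 0.04, with 67 of 129 higher (0.0355). Dividing cell markers went from 0.01 to 0.15, with 79 of 158 higher (0.0262). Jasmonate genes went from -0.03 to 0.06, with 35 of 62 higher (0.0157), but the mean of that difference was -0.26. With an estimated correlation the adjusted p was 0.91 for each of the 9 lists other than heat shock.

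Of these 10 differences only that of the heat shock list passed with each of the 8 libraries left out in turn. It ended with 1 transcript for each gene and an estimated correlation (adjusted p = 0.668). Without control 6 h replicate 2 the calls ended for chaperones (0.497), disulfide isomerases (0.822), proteasome (0.533), jasmonate (0.0818), phenylpropanoids (0.239) and dividing cells (0.806), and autophagy (0.403) and ribosomal proteins (0.3) turned. Without tunicamycin 2 h replicate 2 they ended for chaperones (0.0664), disulfide isomerases (0.184), autophagy (0.0813), ribosomal proteins (0.125), jasmonate (0.576), phenylpropanoids (0.198), auxin (0.511) and dividing cells (0.511). Without tunicamycin 6 h replicate 2 they ended for autophagy (0.0723), proteasome (0.82), ribosomal proteins (0.393), jasmonate (0.0553), auxin (0.0612) and dividing cells (0.82). Without tunicamycin 6 h replicate 1 they ended for chaperones (0.306), disulfide isomerases (0.114), jasmonate (0.0502), phenylpropanoids (0.0747) and auxin (0.114). Without control 2 h replicate 2 they ended for chaperones (0.113), disulfide isomerases (0.194), proteasome (0.0755), jasmonate (0.0613), phenylpropanoids (0.111) and auxin (0.213). Without control 2 h replicate 1 they ended for chaperones (0.0748), disulfide isomerases (0.0748), proteasome (0.0851) and dividing cells (0.403), without tunicamycin 2 h replicate 1 for chaperones (0.16), disulfide isomerases (0.223) and proteasome (0.392), and without control 6 h replicate 1 for auxin (0.223).

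Of the transcripts called with tunicamycin, 15 of 16 at 2 h and 104 of 111 at 6 h were lower, those of jasmonate genes among them, but calls with 1 library left out were 12 up and 1 down without tunicamycin 2 h replicate 2 at 2 h and 17 up and 16 down without tunicamycin 6 h replicate 2 at 6 h, and with no low-count filter 263 up and 416 down at 2 h and 159 up and 438 down at 6 h. Each group held 1 deeper and 1 shallower library, so a difference with depth would largely cancel between the arms. It would move a pair of a deeper control and a shallower tunicamycin library one way and the opposite pair the other way. Of the genes called lower at one time, 97.6% were lower in both such pairs at the other time. These were 9 of 10 genes called at 2 h, all but AOC, and 72 of 73 called at 6 h. The fit that chose the genes took its spread from all 8 libraries, which favours genes with alike deeper and shallower libraries. This check therefore does not decide on depth. Those 9 and 72 genes also had both tunicamycin libraries below both control libraries at the other time, so the 2 counts are 1 observation. Chance gives 16.7% for a single gene chosen without use of that time. Here all 8 libraries entered the fit that chose the genes, 7 genes are in both sets, and genes are not independent tests. Chance values or a swapped library at a single time are therefore left undecided. If a response of the control leaves to handling was the cause, it was not gone by 6 h for most of these genes. The 10 genes called lower at 2 h still had a median change of -2.17 at 6 h (quartiles -2.85 and -1.68, against a median of -2.71 at 2 h). Of them, 7 were called at both times. Whether such a response faded in part is left undecided, as an earlier test had left it. All 10 of 10 also fell from 2 h to 6 h in control leaves (median -0.49), and the later test was chosen with these values known. A handling difference between the arms that lasts to 6 h was not tested and stays open beside an effect of tunicamycin.

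Part of the heat shock and clock genes were called lower at 6 h than at 2 h: 18 and 12 of 73 heat shock genes in tunicamycin and control leaves (25 and 27 lay above zero), and 7 and 5 of 29 clock genes, with 1 clock gene called higher in each arm. The deeper and the shallower libraries of 6 h held more counts than those of 2 h, but depth is argued against as the cause: between the deeper library of 2 h and the shallower of 6 h, where the order of depth is turned, 100% of the heat shock and clock genes called lower in one arm were lower in the other arm (25 of 25 called in tunicamycin leaves, median -2.83 in control leaves, and 17 of 17 called in control leaves, median -4.38 in tunicamycin leaves). Time of day of the harvest may explain the clock genes and stays open. REVEILLE 7, REVEILLE 8, REVEILLE 1 and LHY were called lower in both arms. They gave -5.75, -5.96, -4.84 and -3.79 in tunicamycin and -4.62, -5.68, -3.71 and -4.06 in control leaves. The 8 evening clock genes had a median change of 0.33 in tunicamycin and 0.66 in control leaves, with members going both ways. Among them LOC101256908 (adagio protein 3) rose by 1.85 in tunicamycin leaves (adjusted p = 0.0303) and GIGANTEA by 2.36 in control leaves (adjusted p = 0.0373, a call that ended in 9 of 20 alternatives), while LOC101258346 (GIGANTEA-like) gave -0.67 and 0.45. Time since the start of treatment and time of day cannot be told apart for these genes, since all libraries of a time share both.

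ER chaperone genes were not called higher with tunicamycin at 6 h. In the fit of all 8 libraries the upper 95% bound lay below a log2 change of 2 for 86.7% (13 of 15 genes, and below 1 for 9). The exceptions were LOC101262304 and LOC101256620. Under the spread of that fit, a mean rise of 4-fold is argued against for those 13 genes. That spread is drawn from all groups and from other transcripts, so the bounds do not settle whether 2 libraries in each group are too few. An unlike control library is argued against as the cause of a hidden rise of that size. With 1 of the 4 libraries of 6 h left out the highest chaperone median was 0.49 (without control 6 h replicate 1). It was -0.26 without control 6 h replicate 2, 0.13 without tunicamycin 6 h replicate 1 and 0.16 without tunicamycin 6 h replicate 2. A smaller rise is not excluded, since the sign of the median turned with the control library left out. BiP/grp78 gave 0.25 at 6 h (upper bound 1.09). Its log2 CPM was 6.05 and 4.64 in control 6 h replicates 1 and 2, and 5.89 and 5.61 in tunicamycin 6 h replicates 1 and 2. An exchange of the arm labels at both times, which would turn the direction of each change with tunicamycin, was not tested and stays open, though it would only turn the sign of the chaperone medians (-0.19 at 2 h and 0.15 at 6 h). No biological explanation, such as dose, uptake or the timing of the response, was tested.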

How the results depend on the processing

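Chosen after the data were seen were the depth term, 1 transcript for each gene, removal of ribosomal RNA, the libraries compared without a filter (run for the 3 comparisons the authors tabulated), leaving out libraries for the lists, and for the shared count all but the block and the log2 minimum of 1; the other alternatives were fixed before. The difference between the times uses all 8 libraries, so a fit of only the libraries compared was not run for it. In edgeR the counts of called transcripts were 16 at 2 h, 111 at 6 h, 208 between the times in tunicamycin leaves, 93 in control leaves and 8 shared by both times, and 54 list tests passed. DESeq2 gave 308, 396, 878, 241 and 130 and no filter 679, 597, 1229, 371 and 196, both with all of the 16, 111, 208 and 93. Without a filter 93 also passed in the difference between the times, where edgeR gave 0 (761 at an unadjusted p under 0.05), DESeq2 0 (895) and limma-voom 0 (1172). The prior degrees of freedom were unlimited with no filter, against 10.6. limma-voom gave 1 at 2 h and 1 shared, and the strict filter 9 at 2 h and 4 shared. The replicate number as a block gave 3 at 2 h, 72 at 6 h and 2 shared, and ended 3 of the 54 list calls (ribosomal proteins at 2 h, and disulfide isomerases and the translocon in controls). With only the libraries compared there were 70 at 2 h, 0 at 6 h (1327 at an unadjusted p under 0.05) and 0 shared, and without a filter as well 871 at 2 h, 1220 between the times and 93 shared. Transcripts summed to genes gave 1, 38, 89, 43 and 1 shared, which count genes, and 1 transcript for each gene gave 51, 131 and 51 at 6 h, over time and in controls. The depth term, which pairs the deeper with the deeper and the shallower with the shallower library (between the arms, the crossed replicate numbers), gave 53 at 2 h, 161 at 6 h, 353 over time and 26 shared, and ended 2 of the 54 list calls. Deviations of the same replicate number correlated at -0.085 between the arms at 2 h and -0.19 between them at 6 h. Between the times they correlated at -0.015 in control leaves and 0.18 in tunicamycin leaves, so the numbers were not taken as pairs. Paired by depth instead, the deviations correlated at 0.085 between the arms at 2 h and 0.19 at 6 h, and between the times as before. With the depth term the common biological coefficient of variation was 0.324, against 0.353 without it. RLE, upper-quartile scaling, removal of ribosomal RNA and a log2 minimum of 1 changed none of these counts by over 1.5 times. For the changed counts the cause was not tested.

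With 1 library left out, its arm at that time held a lone sample, assumed to vary like the other groups. The counts then ran from 0 (without control 2 h replicate 2) to 183 (without control 6 h replicate 1) at 2 h, 0 (without tunicamycin 6 h replicate 1, 1592 at an unadjusted p under 0.05) to 194 (without control 6 h replicate 1) at 6 h, 65 (without tunicamycin 2 h replicate 1) to 613 (without control 6 h replicate 1) over time, 23 (without control 2 h replicate 1) to 252 (without control 6 h replicate 1) in controls, 0 to 38 in the difference between the times and 0 to 54 shared (both highest without control 6 h replicate 1).

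List calls rested on the assumed correlation: 4 of 54 passed with an estimated one and 5 by fry. With 1 transcript for each gene 29 of the 54 passed (31 lists in all), and 0 with that and an estimated correlation. With 1 library left out, 30 (without tunicamycin 2 h replicate 2) to 63 (without control 6 h replicate 1) passed. Adjusted p ranges for lists that turned were, at 2 h, 0.000858 to 0.96 for degradation, 0.000135 to 0.971 for photosystems and 0.00116 to 0.943 for ribosomal proteins. At 6 h they were 0.000113 to 0.59 for disulfide isomerases, 1.16e-12 to 0.416 for photosystems, 1.37e-28 to 0.433 for ribosomal proteins and 4.82e-05 to 0.887 for dividing cells. Over time they were 4.16e-06 to 0.994 for ribosomal proteins in tunicamycin leaves, and in controls 0.00125 to 0.79 for disulfide isomerases, 4.23e-18 to 0.798 for ribosomal proteins and 0.00099 to 0.846 for epidermal markers. For the difference between the times they were 1.7e-08 to 0.403 for autophagy and 6.17e-21 to 0.393 for ribosomal proteins.

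None of the named called genes changed direction under any alternative. Their calls ended in 71 of 231 cases at 2 h (11 genes), 177 of 567 at 6 h (27 genes), 24 of 210 over time in tunicamycin leaves (10 genes) and 20 of 139 in controls (7 genes). For transcripts with a mean log2 CPM of at least 1, simulated 2-fold changes were mostly missed (2.99% found at 2 h and 1.49% at 6 h). In these transcripts 4-fold changes were found in 61.2% and 55.2% and 8-fold changes in 90.9% and 92.4%, so a missing call does not exclude a 4-fold effect.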

Other observations

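Leaving out single libraries was chosen for the lists after the data were seen, while the list tests themselves were fixed before. Between 6 h and 2 h, the lists named in this part also passed by camera with the preset correlation, each with an adjusted p of 0.91 (0.928 for ribosomal proteins) with an estimated one. Photosystem and Rubisco genes were lower at 6 h in both arms, with a median of -0.41 in tunicamycin leaves (4 of 74 genes fell, adjusted p = 3.09e-05) and -0.37 in control leaves (2 fell, adjusted p = 4.53e-07). The call in tunicamycin leaves ended without tunicamycin 2 h replicate 2 (0.107) or tunicamycin 6 h replicate 1 (0.538), and the call in control leaves passed with each of the 8 libraries left out in turn.

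In tunicamycin leaves these lists were also lower at 6 h: NAC factors (median -0.37, adjusted p = 0.00656), regulators of the unfolded protein response (-0.10, 0.0133), epidermal markers (-0.23, 0.0162, 4 of 117 genes fell), autophagy (-0.36, 0.0176), ethylene (-0.15, 0.0257, 4 of 155 fell), calcium and wound genes (-0.32, 0.0257) and WRKY factors (-0.33, 0.0413). Ribosomal proteins (0.24, 0.0211) and proteasome subunits (0.29, 0.0229) were higher. Each of these calls ended when certain libraries were left out. Without tunicamycin 2 h replicate 1 they ended for NAC (0.304), epidermis (0.34), ethylene (0.405), calcium (0.265), WRKY (0.671) and proteasome (0.437). Without tunicamycin 2 h replicate 2 they ended for the regulators (0.37) and autophagy (0.0879), and ribosomal proteins turned (0.994). Without tunicamycin 6 h replicate 1 they ended for epidermis (0.114) and ethylene (0.0633). Without tunicamycin 6 h replicate 2 they ended for NAC (0.737), the regulators (0.0672), autophagy (0.0854), calcium (0.0721), WRKY (0.393) and proteasome (0.956), and ribosomal proteins turned (0.473). Ribosomal proteins gave 0.059 and 0.0547 without control 2 h replicates 1 and 2, and without replicate 2 proteasome gave 0.0656.

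In control leaves 4 further lists were lower at 6 h: ribosomal proteins (median -0.03, adjusted p = 0.0178), epidermal markers (-0.15, 0.0194), phenylpropanoids (-0.20, 0.0257) and calcium and wound genes (-0.12, 0.0349). Without control 6 h replicate 2, ribosomal proteins turned higher (2.19e-05), epidermal markers turned without passing (0.846) and phenylpropanoids did not pass (0.398). The calls ended without control 2 h replicate 1 for ribosomal proteins (0.798) and epidermis (0.172), and without control 2 h replicate 2 for epidermis (0.0536), phenylpropanoids (0.213) and calcium (0.213). Without tunicamycin 2 h replicate 2 they ended for epidermis (0.0912) and calcium (0.0518), without tunicamycin 6 h replicate 2 for epidermis (0.0651) and calcium (0.0543), and without control 6 h replicate 1 for calcium (0.257).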
